A study of Rattus norvegicus with 6 samples.

How the data were processed

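RNA was sequenced from primary rat dorsal root ganglion cells, in 3 samples of a control group and 3 of a group kept for 48 h in medium with glucose at 45 mmol/L. Groups and replicate numbers were taken from the sample titles and the extract protocol, and the group with the prefix DM was taken as the high-glucose group, which the labels do not state in those words. The authors deposited one table of mRNA genes and one of lncRNA rows, each with a log2 value per gene and sample. The growth protocol mentions fixation with paraformaldehyde, and the labels do not say whether this applied to the sequenced cells. Per the submitters' processing notes, fastp 0.19.4, HISAT2 2.1.0, featureCounts 1.6.0 and the rat build Rnor_6.0 were used. The notes used here give no role, order or settings, and neither the annotation version nor the strand of the counting was given in the sources used here. Per the deposited file names the values are voom-normalized, and the values themselves are log2 CPM (reads scaled to library size) of the form log2 of reads plus 0.5 over the scaled library size.

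Whole reads could be worked back from the deposited values. Of the values in each table, 100% came within 0.01 of a whole number, with the largest distance at 0.0033 read. The read totals per sample in the report are sums of these reads over the genes of each table. Each table had been scaled on its own genes, so levels and tests were kept within a table. Scaling factors in the mRNA table were 0.959 to 0.964 in control and 1.03 to 1.05 in high glucose. In the lncRNA table they were 1.06 to 1.09 in control and 0.902 to 0.945 in high glucose. The factors of the groups did not overlap in either table, so the size and direction of small changes depend on this scaling. Every gene in both tables had reads in at least 3 of the 6 samples, so genes seen in fewer samples are not analysed here. The median gene had 2282 reads over the 6 samples in the mRNA table and 27 in the lncRNA table, where 638 of 1012 rows had under 60 reads. Genes are named by the symbols that the files pair with Ensembl identifiers, and 105 symbols of the mRNA table stand on more than 1 row. For those the row with the highest mean was used in gene lists. No coordinates are printed, because the gene table at hand was of another assembly (GRCr8). It was used only for gene names, classes and neighbour relations. Of the 1012 lncRNA rows, 28 matched it by symbol as lncRNA, 61 as protein coding and 923 not at all.

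Replicates were compared before they were averaged. A chi-square test of the reads of each pair of samples found differences beyond counting error in every pair, with a mean chi-square per mRNA gene of 3.18 to 5.42 within groups and of 103 to 108 between groups, so no sample was a copy of another. Each was counted as its own replicate, which is an assumption, since the labels do not say whether cultures were separate.

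Gene tests used limma 3.58.1 in R 4.3.3: a linear model with group as its term and moderated statistics with a mean-variance trend, on the deposited log2 values as they stood, two-sided, with Benjamini-Hochberg adjustment over all genes of a table and a threshold of 0.05. The comparisons, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined, except where said below. The lists of cell types and pathways were 55 in number, of which 52 had at least 5 measured members. The lists of lymphocyte and granulocyte markers and of erythroid markers had 4 each, none of which passed, and that of mitochondrially encoded genes had 0. The 52 were tested with cameraPR on the moderated statistics at a preset correlation of 0.01. Camera with an estimated correlation and fry were computed beside it. The neighbour test was a two-sided permutation test of Spearman's rho. Folds of scarce rows were computed on the recovered reads. Where a group had 0 reads, a floor of 3 reads over the group was used and the reads of the other group were taken as exact. Where it had 1 to 3 reads, an exact (Clopper-Pearson) 95% counting interval was given. Other folds are ratios of fitted log2 means, which understate the change of genes near the floor because of the 0.5 read added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

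The genes the text names follow a rule. They are the 10 largest rises and 10 largest falls of the mRNA table, and 5 and 5 of the lncRNA table, among genes past the threshold with a mean log2 value of at least 0 and no overlap between groups. Of each called list, up to 4 members with the smallest p in the direction of the call and up to 2 in the other direction were named. A panel of 15 single genes and the non-coding RNAs that passed were added. Exceptions are said in the text, and 2 members that the rule names are not reported here.

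The gene test was tested on simulated data with the mean reads of the real genes and 1 spread shared by all genes of a table. Far fewer mRNA genes were changed in the simulation than passed in the real data, where 50.5% did. The rates below describe the simulated setting and may differ in the real comparison. In the mRNA table it recovered 25% of genes changed 1.2-fold, 73.9% of those changed 1.5-fold and 76.5% of those changed 2-fold. In the lncRNA table it recovered 1.85% of rows changed 1.2-fold and 6.52% of those changed 1.5-fold. There it recovered 28.1% of rows changed 2-fold and 62.8% of those changed 4-fold. Of 16200 unchanged mRNA genes 11 were called, and of 765 unchanged lncRNA rows 4.

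The alternatives were a replicate block, filters on low values, quantile normalization, centring on medians, other variance priors, sample weights, leaving out each sample, other thresholds, both tables in one fit, other list tests, and other distances between neighbours. Chosen after seeing the data were voom weights from the recovered reads, lncRNA reads on the mRNA scale, leaving out lncRNA rows with a protein-coding symbol, and an adjusted p under 0.05 with a log2 fold change of at least 1.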

Results

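Primary cells of rat dorsal root ganglia, the clusters of sensory neurons and their supporting cells beside the spinal cord, were grown for 48 h either in control medium or in medium with glucose at 45 mmol/L. RNA abundance was measured by sequencing in 3 control samples and 3 high-glucose samples, and the values were deposited as a table of mRNA genes and a table of long non-coding RNA (lncRNA) rows. The labels call the 3 samples of a group duplicates and do not say whether they came from separate cultures or animals. The p-values therefore measure only the spread between these samples, which may be technical. The mRNA table held 16551 genes and between 28780612 and 33108451 reads per sample. The lncRNA table held 1012 rows, with 345740 to 389628 reads per control sample and 497327 to 556411 per high-glucose sample. The glucose level of the control medium was not given, and no sample controlled for osmolarity. Each log2 fold change below is high glucose minus control, given with its standard error (SE), and rests on 3 samples per group.

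The comparison asked which mRNAs differed between cultures in high glucose and in control medium. Among the genes higher in high glucose were Aqp1, a water channel (2.93-fold), and Lum, a proteoglycan (4.45-fold). Among those lower were Slc7a5, an amino acid transporter subunit (2.46-fold), and Gap43, a growth cone protein (6.49-fold). Of the 16551 genes, 8354 passed the limma test at an adjusted p under 0.05, 4126 of them higher and 4228 lower in high glucose. Most of the changes were small. The median absolute log2 fold change of the genes that passed was 0.376, and 5706 of them changed by less than 1.5-fold, while 1365 changed by at least 2-fold (786 higher, 579 lower). The 3 samples of one group lay entirely above the 3 of the other in 57.6% of all genes, where chance gives 10%. Pearson correlations between samples across genes were 0.985 to 0.986 within a group and 0.972 to 0.974 between groups. The most abundant transcripts in both groups, singled out after their values were seen, encoded collagens and other proteins of connective tissue and cytoskeleton. Col1a1, a chain of type I collagen, took 3.35% ± 0.11 (SD, n = 3) of the mRNA reads in control and 2.72% ± 0.12 in high glucose, and Col3a1, the chain of type III collagen, went the other way, from 1.92% ± 0.029 to 2.53% ± 0.029.

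The largest rises in high glucose were led by Fxyd2 (ENSRNOG00000016469), a regulatory subunit of the sodium pump, which was 27.1-fold higher with a log2 fold change of 4.76 ± 0.35 (adjusted p = 9.53e-08). Gna14 (ENSRNOG00000014840), a G-protein alpha subunit, rose 18.98-fold (4.25 ± 0.08), and Cnnm1, of the cyclin M family, rose 18.03-fold (4.17 ± 0.23). Islr, Aspn and Clec3b, all of which encode secreted or matrix proteins, rose by log2 fold changes of 3.82 ± 0.06, 3.72 ± 0.36 and 3.50 ± 0.22. Mrgprf, an orphan receptor of the Mas-related family, rose by 3.60 ± 0.07. Xdh, the enzyme that makes uric acid, rose by 3.33 ± 0.10, Tyrp1, an enzyme of melanin synthesis, by 3.30 ± 0.22, and Arxes2 by 3.24 ± 0.19. Among the largest falls, Gap43 (ENSRNOG00000001528) was 6.49-fold lower, with a log2 fold change of -2.70 ± 0.23 (adjusted p = 3.46e-07). Prph, the intermediate filament of peripheral neurons, had a log2 fold change of -2.67 ± 0.19, and Slc17a6, the vesicular glutamate transporter VGLUT2, one of -2.55 ± 0.18. The transcription factors Sox11 and Dach1 had values of -2.65 ± 0.09 and -2.66 ± 0.27, and Ncan, the matrix proteoglycan neurocan, -2.63 ± 0.07. The other large falls were Ptprb (ENSRNOG00000055293), a receptor phosphatase of vascular endothelium (-3.05 ± 0.12), Ifi27l2b (-2.63 ± 0.16), Pappa2, a protease of insulin-like growth factor binding proteins (-2.49 ± 0.21), and Ednrb, an endothelin receptor (-2.48 ± 0.14). Several of these genes were scarce: Fxyd2 had 28 reads over the 3 control samples and 776 over the 3 high-glucose samples, and Gap43 had 481 and 82.

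**Figure D1:**
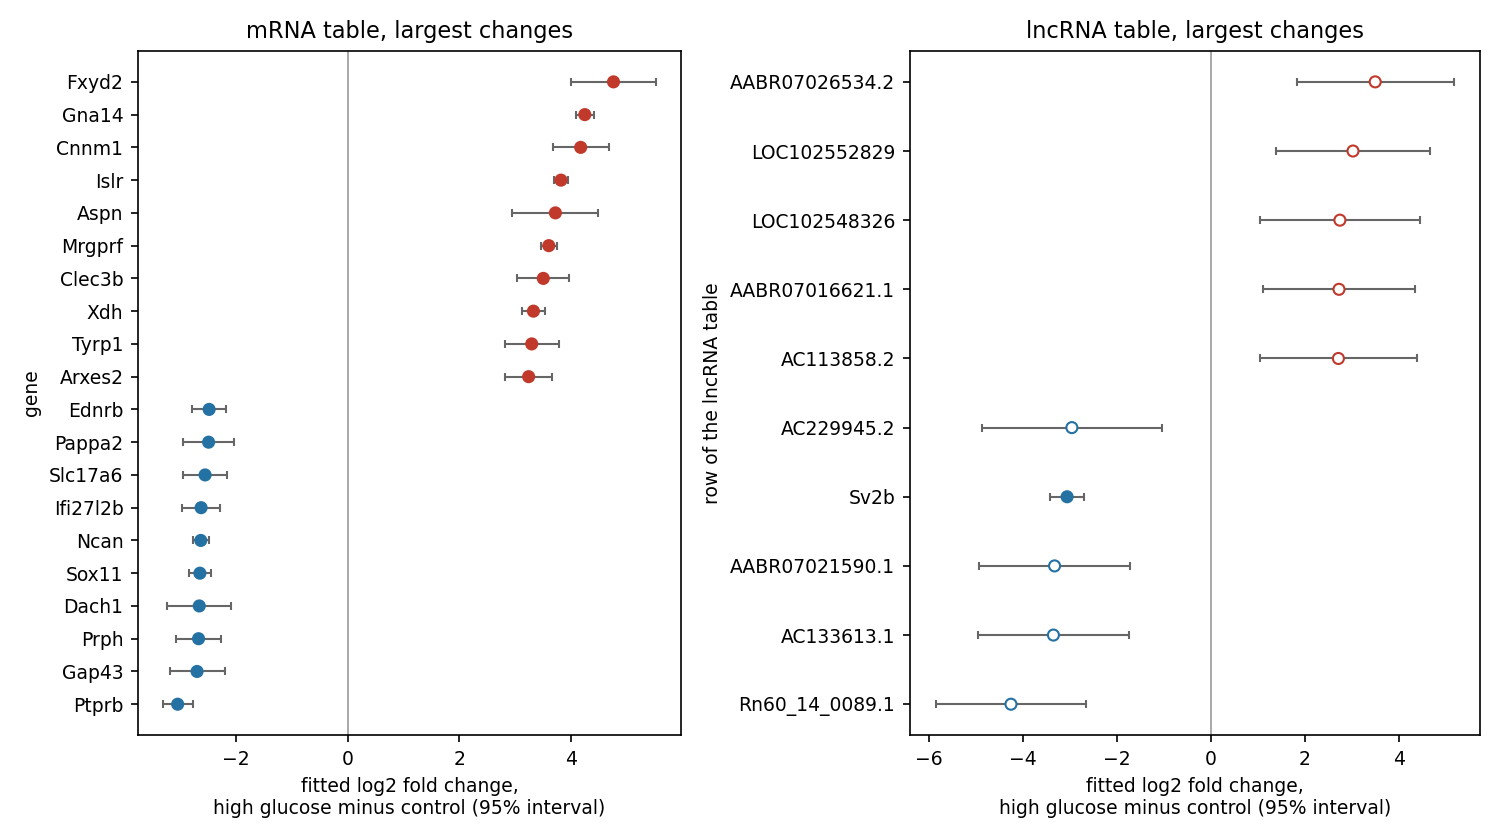
Fitted log2 fold changes (high glucose minus control, horizontal axis) with 95% intervals for the 10 largest rises and 10 largest falls of the mRNA table (left) and the 5 and 5 of the lncRNA table (right), red for higher and blue for lower. Hollow points mark rows with 3 reads or fewer over the 3 samples of one group, whose fitted value is no bound on the fold; the mRNA values run from 4.76 for Fxyd2 to -3.05 for Ptprb.

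Fixed gene lists of cell types and pathways were tested with cameraPR in limma at a preset correlation of 0.01. Of 52 lists tested, 16 were called, 4 higher and 12 lower in high glucose. None of the 16 calls held with a correlation estimated from the samples, where the lowest adjusted p was 0.0663, so that p is given beside each list. The estimates for these lists ran from -0.0483 for the amino acid response to 0.224 for repair Schwann cell markers. For lists with an estimate below the preset 0.01, such as the amino acid response, a stronger correlation was not what ended the call. What ended it there was not tested. Groupings of the 6 samples other than by treatment gave up to 9 calls at the preset correlation. Those groupings mix both treatments unevenly and keep part of the treatment difference, so 9 is not a count of false calls. Counts of members are over all genes tested, and the counts adjusted over the list alone were equal to them except where given.

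Genes that cells induce under osmotic stress through the transcription factor NFAT5 rose. Of 12 measured, 10 rose and 1 fell, with a median log2 fold change of 0.53 (adjusted p = 3.7e-11 for the list, adjusted p = 0.119 with an estimated correlation). Aqp1, a water channel, rose 2.93-fold (1.55 ± 0.02), Slc38a2, an amino acid transporter, rose 1.47-fold (0.55 ± 0.02), and Nfat5 itself rose 1.45-fold (0.54 ± 0.02). Slc2a1, the glucose transporter GLUT1, rose by 0.69 ± 0.03. The member that fell was Pfkfb3, a regulator of glycolysis (-0.14 ± 0.05, adjusted p = 0.0229). Its adjusted p ranged from 0.011 to 0.103 over the alternatives and lay above 0.05 without control 1 (0.103), high glucose 1 (0.0649) or high glucose 3 (0.0889), and with a single variance prior for all genes (0.0817). Akr1b1, the aldose reductase that turns glucose into sorbitol, rose 1.81-fold (0.85 ± 0.04), and Txnip, a thioredoxin-binding protein induced by glucose, rose 1.48-fold (0.57 ± 0.03). Slc5a3 was not measured. Genes of glycolysis fell: 15 of 23 fell and 4 rose, with a median of -0.33 (adjusted p = 0.000171, and adjusted p = 0.189 with an estimated correlation). Aldoa, Eno1 and Gapdh had log2 fold changes of -0.63 ± 0.02, -0.59 ± 0.02 and -0.57 ± 0.02 (-0.36 for Gapdh after quantile normalization), and Hk2, which phosphorylates glucose on entry, -0.73 ± 0.03. Slc2a1, a member of this list too, and Pfkm (0.42 ± 0.04) went the other way.

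Genes of the amino acid and integrated stress response fell together. Of 20 measured, 17 fell and none rose, with a median log2 fold change of -0.73 (adjusted p = 3.58e-23, and adjusted p = 0.0663 with an estimated correlation). Atf4, the transcription factor at the centre of this response, was 1.64-fold lower (-0.71 ± 0.02). The amino acid transporter subunits Slc7a5 and Slc3a2 were 2.46-fold and 1.69-fold lower (-1.30 ± 0.03 and -0.76 ± 0.02), and Sesn2, a stress-induced inhibitor of growth signalling, was 1.99-fold lower (-0.99 ± 0.03). Genes of the unfolded protein response of the endoplasmic reticulum had a median of -0.27, with 19 of 23 lower and none higher, or 20 lower when adjusted over the list alone (adjusted p = 6.27e-07, and adjusted p = 0.13 with an estimated correlation). The chaperones Hspa5 and Hsp90b1 had values of -0.57 ± 0.02 and -0.44 ± 0.02 (-0.32 and -0.18 after quantile normalization), the degradation factor Sel1l -0.35 ± 0.02, and the stress transcription factor Ddit3 -0.98 ± 0.06.

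Most cytosolic ribosomal protein genes were lower. Of 71 measured, 62 fell, 1 rose and 8 did not pass, with a median of -0.28 (adjusted p = 2.36e-13, and adjusted p = 0.161 with an estimated correlation). Rpl13, Rps3a, Rpl14 and Rpl7 had log2 fold changes between -0.44 ± 0.02 and -0.40 ± 0.02 (-0.26 for Rpl7 after quantile normalization), and the member that rose was Rpl13a (0.34 ± 0.04). Replication-dependent histone genes, which are expressed in S phase, fell in 19 of 21 cases and rose in none, or fell in 20 when adjusted over the list alone, with a median of -0.60 (adjusted p = 1.49e-07, and adjusted p = 0.0663 with an estimated correlation). Hist1h2bo and Hist1h1b were 2.18-fold and 2.07-fold lower (-1.12 ± 0.04 and -1.05 ± 0.04), and Hist1h4m and Hist1h2bk had values of -0.63 ± 0.03 and -0.62 ± 0.04. Both families hold near-identical copies among which the counting could split reads, so single members are uncertain. Of the genes of proliferation, 19 of 29 fell and 1 rose, or 20 fell when adjusted over the list alone, with a median of -0.17 (adjusted p = 0.0303, and adjusted p = 0.119 with an estimated correlation). Ccna2 and Ube2c, of the cell cycle machinery, had values of -0.58 ± 0.03 and -0.51 ± 0.06, Mki67 and Cenpf -0.24 ± 0.02 and -0.22 ± 0.02 (-0.10 for Mki67 after quantile normalization), and Kif20a rose by 0.19 ± 0.04. The proliferation call ended when genes with a mean log2 value under 0 were left out (adjusted p = 0.0998), when the lowest 25% of genes was left out (0.095) and after quantile normalization (0.0886), within a range of 4.88e-05 to 0.119 over its alternatives.

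**Figure D2:**
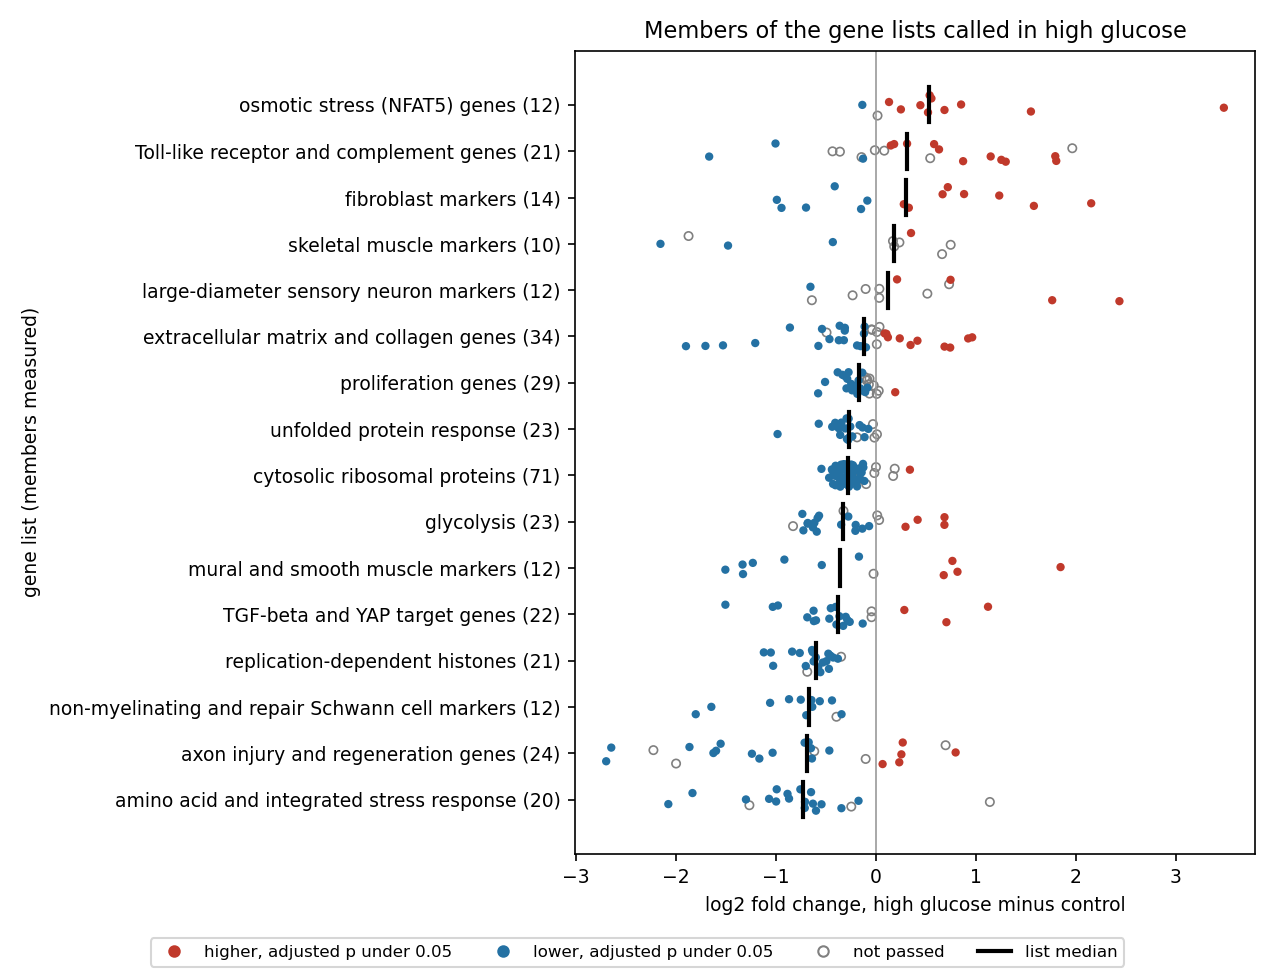
Log2 fold changes (high glucose minus control, horizontal axis) of the measured members of the 16 called gene lists (vertical axis, number measured in brackets), with filled points for members at an adjusted p under 0.05, red for higher and blue for lower, hollow points for members that did not pass, and a black bar at each list's median. The medians run from -0.73 for the amino acid and integrated stress response to 0.53 for the osmotic stress genes, and members of several lists, such as extracellular matrix genes, lie on both sides of 0.

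Genes of axon injury and regeneration, which injured sensory neurons and glia switch on, were lower. Of 24 measured, 14 fell and 5 rose, or 16 and 6 adjusted over the list alone, with a median of -0.69 (adjusted p = 0.00108, and adjusted p = 0.161 with an estimated correlation). Sox11 was 6.26-fold lower, Cacna2d1, the calcium channel subunit bound by gabapentin, 2.36-fold lower (-1.24 ± 0.05), and Tubb6, a tubulin, and Tnfrsf12a, a receptor, had values of -0.64 ± 0.02 and -0.67 ± 0.03. Flrt3 (0.80 ± 0.05) and Stat3 (0.27 ± 0.02) rose. Atf3, the transcription factor best known as an injury marker of sensory neurons, was 2.24-fold lower (-1.17 ± 0.07). Neuronal transcripts were scarce: the median level of 20 pan-neuronal markers was -0.30 on the log2 CPM scale of reads per library size, and that of 18 nociceptor markers was -2.81. Of the pan-neuronal markers, 9 were lower, or 11 adjusted over the list alone, and 2 were higher, with a median log2 fold change of -1.34. Of the nociceptor markers 6 were lower and 2 higher, with a median of -1.20. It was -1.02 with the 2 members at 0 reads in a group taken against the floor of 3 reads. Neither list was called by cameraPR (adjusted p = 0.157 and 0.647), whereas fry, which does not compare a list with other genes, called both (adjusted p = 0.000398 and 0.00526). Scn9a, the sodium channel Nav1.7, was 3.42-fold lower on 37 reads against 119 (-1.77 ± 0.26, adjusted p = 6.96e-05). Calca, which encodes the neuropeptide CGRP, had a value of -1.02 ± 0.33 (adjusted p = 0.0209), which ranged from 0.00636 to 0.0917 over the alternatives and lay above 0.05 without control 2 (0.083), control 3 (0.0781) or high glucose 1 (0.0917) and with a single variance prior (0.0832). Scn10a, the sodium channel Nav1.8, had 3 reads in high glucose and 16 in control, a ratio of 5.77 with an exact 95% counting interval of 1.65 to 30.9 (adjusted p = 0.0322). That p ranged from 0.0195 to 0.153 and lay above 0.05 without control 1 (0.153), control 2 (0.0804) or high glucose 1 (0.11), with a single variance prior (0.0796) and with a replicate block (0.053). P2rx3, an ATP receptor of pain-sensing neurons, rose 2.23-fold (1.16 ± 0.14, adjusted p = 1.22e-05), and Trpv1, the capsaicin receptor, had a value of -0.53 ± 0.31 that did not pass (adjusted p = 0.176). The list of large-diameter sensory neuron markers was called higher, with 4 of 12 higher, 1 lower and a median of 0.12 (adjusted p = 8.32e-10, and adjusted p = 0.325 with an estimated correlation). The members that rose were Spp1, the secreted protein osteopontin that many cell types make (2.44 ± 0.02, at 11.9 log2 CPM in high glucose), Ntrk2 and Ntrk3, neurotrophin receptors (1.76 ± 0.05 and 0.75 ± 0.16), and Piezo2, a touch channel (0.21 ± 0.02). Etv1 fell (-0.66 ± 0.08). The median of this list moved to 0.30 without control 3, 0.235 without high glucose 1, 0.25 without high glucose 3 and 0.48 without scarce genes.

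Markers of other cells of the ganglion moved in the same comparison. Markers of non-myelinating and repair Schwann cells were lower in 11 of 12 cases and higher in none, with a median of -0.67 (adjusted p = 1.21e-07, and adjusted p = 0.204 with an estimated correlation). The adhesion molecules L1cam and Ncam1 were 3.13-fold and 1.83-fold lower (-1.65 ± 0.05 and -0.87 ± 0.02), and the receptors Ngfr and Erbb3 had values of -0.64 ± 0.04 and -0.56 ± 0.04. The list of mural and smooth muscle markers fell as well, with 7 of 12 lower, 4 higher and a median of -0.36 (adjusted p = 1.17e-14, and adjusted p = 0.482 with an estimated correlation). The median was -0.17 without genes of a mean log2 value under 0 and -0.06 after quantile normalization, where the call held. The contractile genes Myh11, Acta2 and Cnn1 were 2.84-fold, 2.35-fold and 1.89-fold lower, and Cspg4, the pericyte marker NG2, was 2.52-fold lower (-1.33 ± 0.02), whereas Abcc9 (0.82 ± 0.06) and Notch3 (0.76 ± 0.04) rose. The list of targets of TGF-beta and of YAP, which respond to the growth factor and to mechanical tension, fell in 17 of 22 cases and rose in 3, with a median of -0.38 (adjusted p = 1.31e-16, and adjusted p = 0.259 with an estimated correlation). The list also holds genes of growth factors, Tgfb2, Tgfb3 and Bmp4, so it does not report on targets alone. Among its members Tgfb3 was 2.84-fold lower (-1.51 ± 0.02) and Thbs1 1.97-fold (-0.98 ± 0.02, and -0.53 after quantile normalization), Tgfb2 had a value of -0.62 ± 0.02, and Bmp4 (1.12 ± 0.05) and Id2 (0.70 ± 0.04) rose.

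Fibroblast markers split into 8 that rose and 6 that fell, with a median of 0.30 (adjusted p = 0.00371, and adjusted p = 0.482 with an estimated correlation). The proteoglycans Lum and Dcn were 4.45-fold and 2.35-fold higher (2.15 ± 0.03 and 1.23 ± 0.04), and Pdgfra (0.88 ± 0.02) and the collagen cross-linking enzyme Lox (0.72 ± 0.02) rose too. Postn and Col5a1 fell (-0.99 ± 0.02 and -0.70 ± 0.03). Extracellular matrix and collagen genes were called lower, but 10 of 34 rose beside 18 that fell, with a median of -0.12 (adjusted p = 0.00308, and adjusted p = 0.55 with an estimated correlation). After quantile normalization the median was 0.04 and the list was not called (adjusted p = 0.145), and with a single variance prior its adjusted p was 0.0566, within a range of 0.000102 to 0.55. Tnc, tenascin C, was 3.73-fold lower (-1.90 ± 0.02), Fbln2 2.31-fold (-1.21 ± 0.02), and Eln, elastin, and Fbln5 had values of -0.86 ± 0.03 and -0.54 ± 0.02, while Emilin1 (0.96 ± 0.03) and the protease Mmp2 (0.92 ± 0.02) rose.

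Toll-like receptor and complement genes were called higher, with 11 of 21 higher, or 12 adjusted over the list alone, 3 lower and a median of 0.31 (adjusted p = 0.0107, and adjusted p = 0.325 with an estimated correlation). Genes of the complement system were among those higher: C1s was 3.49-fold higher (1.80 ± 0.12), Serping1 2.22-fold (1.15 ± 0.11) and C1r 1.83-fold (0.87 ± 0.03). C3 fell (-1.67 ± 0.20), and Tlr9 had a value of -1.005 ± 0.366 on 24 and 45 reads (adjusted p = 0.0357), which ranged from 0.0162 to 0.115 over the alternatives and lay between 0.0542 and 0.115 on leaving out any sample except high glucose 2, and at 0.0554 with a replicate block. Il6 was 1.90-fold lower (-0.93 ± 0.10), Hmox1, the heme oxygenase induced by oxidants, was 1.502-fold lower (-0.59 ± 0.04), and neither Nlrp3 (0.22 ± 0.12, adjusted p = 0.128) nor Ager, the receptor for glycated proteins (-0.26 ± 0.13, adjusted p = 0.122), passed. Nlrp3 passed without high glucose 1 (0.33, adjusted p = 0.0306, within a range of 0.0306 to 0.376). Ager passed after quantile normalization (0.0326, within a range of 0.0326 to 0.299), and Trpv1 passed with a single variance prior (0.0456, within a range of 0.0456 to 0.394). The list of skeletal muscle markers was called lower although its median was 0.18, while its mean was -0.36, with 3 of 10 lower and 1 higher (adjusted p = 0.0188, and adjusted p = 0.488 with an estimated correlation). Myh2 was 4.45-fold lower (-2.16 ± 0.04), Acta1 2.79-fold (-1.48 ± 0.05) and Casq1 1.35-fold (-0.43 ± 0.11), Tnnt3 rose (0.35 ± 0.09), and Ckm had 1 read in high glucose and 8 in control and did not pass (adjusted p = 0.1). The median of this list had the other sign without control 1 (-0.22), high glucose 1 (-0.01) or high glucose 2 (-0.13), lay at 0.02 without control 2 and 0.33 without control 3, and was 0.06 after quantile normalization, while the test called the list lower in each of these cases.

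**Figure D3:**
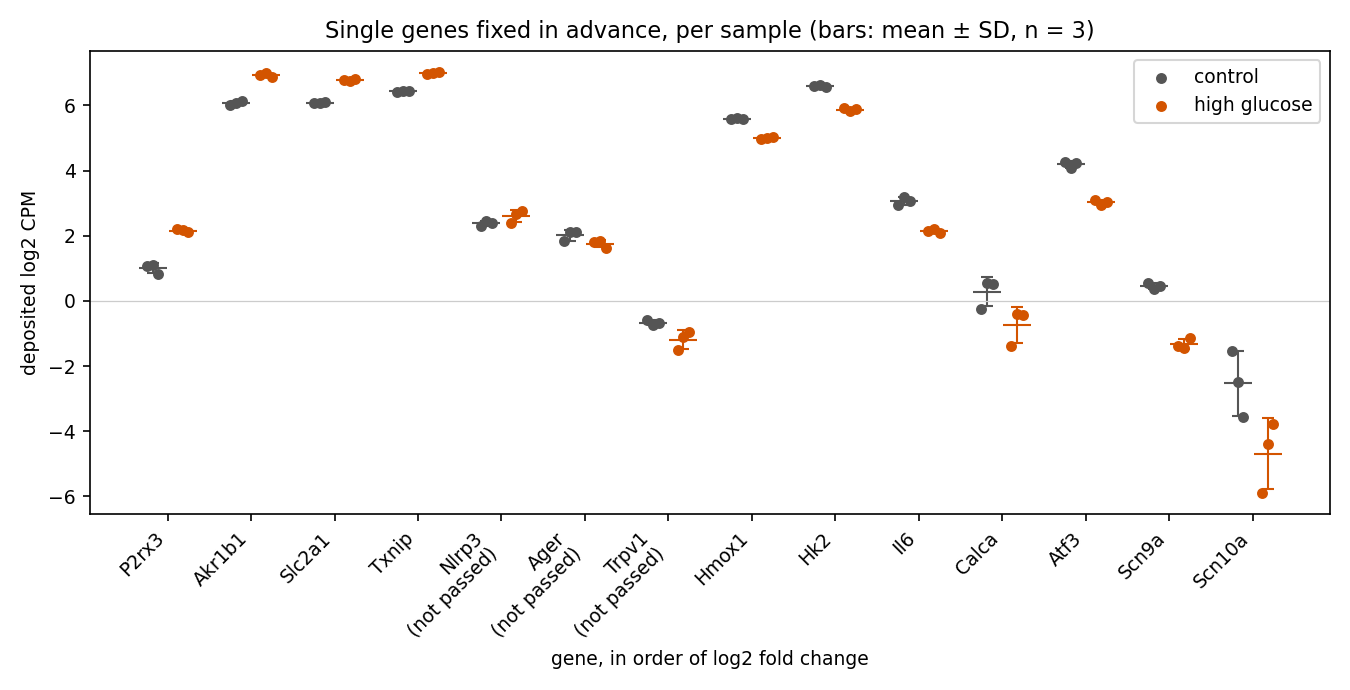
Deposited log2 CPM (vertical axis) of the 14 measured single genes of the fixed panel, with 1 point per sample, grey for control and orange for high glucose, and bars at the mean ± SD (n = 3). The groups of Akr1b1, Slc2a1, Txnip and P2rx3 lie apart with high glucose on top. Those of Hk2, Hmox1, Il6, Atf3, Scn9a, Calca, Scn10a and Trpv1 lie apart with control on top, although Trpv1 did not pass. Nlrp3 and Ager, whose groups overlap, did not pass either.

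The same question was asked of the 1012 rows of the lncRNA table, tested within that table because it was scaled on its own. At an adjusted p under 0.05, 130 rows passed, 56 higher and 74 lower in high glucose, and 58 of them changed by at least 2-fold on the fitted scale (28 higher, 30 lower). Of the 130, 27 carried a symbol that RefSeq lists as protein coding, and none of the 61 such rows appeared by name in the mRNA table. The strand of the counting was not given in the sources used here, so reads of a row and of a gene overlapping it on the other strand cannot be told apart. A group of 3 rows, Rn60_1_2212.2, Rn60_1_2212.3 and Rn60_1_2212.4, singled out after their values were seen, took 61.7% ± 0.24 (SD, n = 3) of the reads in control and 73.2% ± 0.29 in high glucose, with log2 fold changes of 0.47 ± 0.02, 0.41 ± 0.04 and 0.48 ± 0.04. What these rows encode, and whether they are lncRNAs, could not be determined from the files. Scaled by the mRNA libraries, which moved the median row by 0.18, 134 rows passed, 87 higher and 47 lower, and 103 of them were among the 130. The count was 49 with a single variance prior (30 higher, 19 lower), 281 when both tables were fitted together (145 higher, 136 lower), and 86 without high glucose 1.

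The lncRNA rows with the largest changes were mostly near the limit of detection. Sv2b (ENSRNOG00000011160), whose symbol belongs to a synaptic vesicle protein, was 8.30-fold lower (-3.05 ± 0.17, adjusted p = 7.21e-09) on 132 reads in high glucose and 869 in control. Rn60_14_0089.1 had 0 reads in high glucose and 22 in control, which makes it 9.01-fold lower against a floor of 3 reads over the group. Folds against this floor take the reads of the other group as exact, so they are no lower limits. AC133613.1 and AABR07021590.1 each had 0 and 11 reads and were 4.50-fold lower against the floor. AABR07026534.2 had 22 reads in high glucose and 0 in control and was 5.97-fold higher against the floor. LOC102552829, with 14 and 0 reads, was 3.80-fold higher against it. AC113858.2 and AABR07016621.1, with 12 and 11 reads against 0, were 3.26-fold and 2.98-fold higher against the floor. LOC102548326 had 17 and 1 reads, a ratio of 13.8 with a counting interval of 2.17 to 578. AC229945.2 had 3 and 17 reads, 6.96-fold lower with an interval of 2.01 to 37.1. The calls of the last 4 each ended on leaving out any of 5 of the 6 samples, with adjusted p-values of 0.0514 to 0.0835 for AABR07016621.1, 0.0559 to 0.112 for AC113858.2, 0.079 to 0.105 for LOC102548326 and 0.095 to 0.134 for AC229945.2. Over all alternatives these p-values ranged from 4.5e-05 to 0.0835, from 0.000819 to 0.112, from 0.00164 to 0.105 and from 0.00881 to 0.138. The exceptions were high glucose 3 for AABR07016621.1, high glucose 1 for AC113858.2 and AC229945.2, and control 2 for LOC102548326. These intervals cover counting error only, and the folds against the floor do not cover it.

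Of a fixed list of 55 non-coding RNAs, 3 were matched by name in either table, and Malat1, Neat1, Meg3 and H19 were not among them. Pvt1, the RNA transcribed beside Myc, was 1.31-fold lower (-0.39 ± 0.07, adjusted p = 0.00153). Its call ended after quantile normalization (-0.10, adjusted p = 0.481), with a single variance prior (0.296) and on the mRNA scale (-0.20, adjusted p = 0.0609), within a range of 5.31e-07 to 0.481. Tug1 was 1.12-fold higher (0.16 ± 0.05, adjusted p = 0.0378), and its call ended on leaving out any of the 6 samples (adjusted p = 0.0577 to 0.147), within a range of 6.01e-05 to 0.64 over all its alternatives. It ended too after centring on medians (0.09, adjusted p = 0.475), with a single variance prior (0.64), with a replicate block (0.0861) and without rows of protein-coding symbols (0.0876), while on the mRNA scale the value was 0.35 (adjusted p = 6.01e-05). Snhg11 had 7 and 3 reads and did not pass (adjusted p = 0.376).

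The last comparison asked whether lncRNAs moved with the protein-coding genes beside them. By name, 28 rows could be placed as lncRNAs in RefSeq (assembly GRCr8, used for neighbour relations only), and 25 had a measured protein-coding neighbour within 100 kb. Across these 25 pairs of genes, which are not independent replicates, Spearman's rho between the log2 fold changes was 0.416 (two-sided permutation test with 100000 re-pairings, p = 0.0397), and 16 pairs had the same sign. Only 7 of the lncRNAs in these pairs had passed, so most of the lncRNA changes that were ranked were not calls. The pair of Pvt1 and Myc had values of -0.39 and -0.96. Other pairs with both members past the threshold, singled out after their values were seen, went both ways. LOC102549948 with Tram2 and LOC102550036 with Picalm moved alike. LOC102549726 with Hspa1b and LOC100910237 with Rps12 moved in opposite directions. Within 10 kb rho was 0.547 over 16 pairs (p = 0.0306). The relation no longer passed within 1000 kb (rho = 0.308, p = 0.111), without overlapping neighbours (0.317, p = 0.133), without control 1 (0.322, p = 0.117), without control 2 (0.332, p = 0.105) and without high glucose 3 (0.372, p = 0.0679).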

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

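The settings with voom weights, with lncRNA reads on the mRNA scale, without protein-coding symbols and with both an adjusted p and a fold threshold were chosen after seeing the data, and the others before. The count of mRNA genes, 8354, ranged from 7462 without high glucose 1 to 7793 without control 3 on leaving out a sample, and was 1542 at an unadjusted p with at least a 2-fold change and 1365 at an adjusted p with that change. The lncRNA count, 130, ranged from 86 to 110 without a sample, and was 49 with a single variance prior, 281 in one fit with the mRNA table and 58 at an adjusted p with a 2-fold change. Of the passing rows 43.1% were higher, against 64.9% on the mRNA scale, 61.2% with a single prior, 53% after quantile normalization and 51.6% in one fit. The percentage was lower after centring on medians (34.2%) and on leaving out a sample (36.3% to 41.3%). Of the 49 rows called with a single prior, 34 were among the 130. Gene lists called, 16, were 0 with an estimated correlation and 41 with fry, which asks only whether a list moves, and 16 to 17 without a sample. After quantile normalization 50 of the 8354 mRNA genes changed sign. The extracellular matrix list turned to a median of 0.0428 after quantile normalization. The neighbour relation, 0.416, was 0.547 within 10 kb, 0.308 within 1000 kb, 0.317 without overlapping neighbours and 0.322 to 0.449 without a sample. With each of these settings the cause was not tested, except that a fold threshold beside the same adjusted p leaves fewer genes by construction. Leaving out a sample can also add calls: without control 1, 17 lists passed.

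The data gave no consistent pairing by replicate number: the deviations of same-numbered samples correlated at 0.00224, -0.0145 and 0.0136 over all mRNA genes and at 0.106, 0.131 and -0.142 over those at or above the median level, and not every sample correlated best with its own number. With a replicate block, 8052 mRNA genes, 139 lncRNA rows and 17 lists passed, and rho was 0.416. Of the named mRNA genes, Scn10a (adjusted p = 0.053) and Tlr9 (0.0554), and of the lncRNAs Tug1 (0.0861), lay above the threshold with the block. Over all alternatives, values of named mRNA genes kept their direction and side of the threshold in 1661 cases, lost the call in 19 and gained it in 3. For named lncRNA rows these were 174, 37 and 0, and for lists 249, 20 and 0 beside the 1 turn above. Depth limits the lncRNA table, where 63% of rows had under 60 reads over the 6 samples, more than the mRNA table, where 17.2% of genes did.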

Other observations

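Several lists that cameraPR did not call still held members that moved. Of all mRNA genes 50.5% passed, so members that moved do not by themselves set a list apart. Counts adjusted over the list alone were equal to those over all genes except where given. Of 33 genes of synaptic vesicles and neurotransmission, 16 fell and 6 rose, or 17 and 7 adjusted over the list alone (median log2 fold change -0.76, adjusted p = 0.647 for the list in limma's cameraPR). Of 26 neurotrophic factors and their receptors, 15 fell and 8 rose (median -0.43, adjusted p = 0.906). NRF2 targets, which respond to oxidants, fell in 14 of 19 cases and rose in 2 (median -0.30, adjusted p = 0.132), and antioxidant enzymes fell in 10 of 19 and rose in 3, or 4 adjusted over the list alone (median -0.11, adjusted p = 0.963). Genes of the pentose phosphate pathway fell in 7 of 10 cases and rose in 1 (median -0.26, adjusted p = 0.053).

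Other lists that were not called leaned lower, leaned higher or went both ways. Proteasome subunits fell in 20 of 31 cases and rose in 1 (median -0.12, adjusted p = 0.0868 in cameraPR). Nuclear-encoded subunits of oxidative phosphorylation fell in 21 of 50 and rose in 4 (median -0.09, adjusted p = 0.4). Glucose-responsive targets of ChREBP and MondoA rose in 7 of 16 cases and fell in 2 (median 0.21, adjusted p = 0.141), and interferon-stimulated genes rose in 11 of 29 and fell in 4 (median 0.17, adjusted p = 0.4). Of 18 targets of p53, 10 rose and 5 fell (median 0.28, adjusted p = 0.423), and of 24 genes of myelin lipid and cholesterol synthesis 10 rose and 9 fell (median 0.03, adjusted p = 0.577). Satellite glia markers split into 4 higher and 4 lower of 13 (adjusted p = 0.593), myelinating Schwann cell markers into 1 higher and 5 lower of 14 (adjusted p = 0.129), and of 14 macrophage markers 2 rose and 3 fell (adjusted p = 0.963). Of 14 voltage-gated sodium channel genes 2 rose and 4 fell (adjusted p = 0.963).

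Of the tests in the paragraphs that follow, those of the splits were written before the result was seen, and those of the 3 patterns after it. The 6 samples make 10 splits of 3 against 3, too few for a share under 0.05, and in each of the 3 results 1 split, the real one, gave a count as large. The real split gave 8354 mRNA genes against a highest other of 0, 130 lncRNA rows against 1, and 16 gene lists against 9. The other splits mix both treatments unevenly and keep part of their difference, so their counts are no reference without treatment.

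Neuronal markers were lower in high glucose in most cases that passed: of 38 pan-neuronal and nociceptor markers measured, 19 passed, 15 lower and 4 higher. A loss of neurons alone would lower every marker that only neurons make. The 4 that were higher do not decide this, because which markers other cells of these cultures also make was not known. Of the 19 markers with at least 100 reads, 10 passed lower, 3 passed higher and 6 did not pass. The median log2 fold change of these 19 was -0.419, against -0.00401 for 13055 other genes with as many reads (two-sided permutation p = 0.00015 over genes taken as independent). This argues against too few reads as the whole source. The full lists had medians of -1.34 and -1.2, so the fall was smaller among the well-read markers. CameraPR called neither full list (adjusted p = 0.157 and 0.647, and 0.259 and 0.482 with an estimated correlation). For the 15 that fell, fewer neurons and lower expression per neuron cannot be told apart: their changes spanned a range of 3.30, and which of them other cells of these cultures also make was not known. High glucose, or its osmolarity, may have acted on either, which the design leaves untested.

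The split of passing lncRNA rows, 43.1% of which were higher, was not stable between settings. Scaling the reads by the mRNA libraries raised that percentage by 21.8 points, but it shifts all rows upward. Centring on medians, which shifts rows downward, lowered the percentage to 34.2%. Neither move decides whether the scaling of the table is the source. Settings that left the scaling alone moved the percentage too, to 61.2% with a single variance prior and 51.6% in one fit with the mRNA table. The rise of the 3 most abundant rows stays open as well: the other rows with a mean log2 value of at least 5 had a median log2 fold change of -0.0697, but the deposited scaling centres them. An effect of high glucose on lncRNAs as a class stays open.

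Amino acid response and ribosomal protein genes were lower in high glucose than the other mRNA genes, by differences of medians of -0.746 and -0.289 (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give, and 3e-05). One shift of all genes by the scaling would not make such differences. Both lists had been called by cameraPR, which also compares a list with the other genes, so these p-values restate the calls and add no support. These permutations take genes as independent, and the lists had an adjusted p = 0.0663 and an adjusted p = 0.161 with an estimated correlation. The ribosomal proteins fell more than the subunits of oxidative phosphorylation, with a difference of -0.182 (permutation p = 1e-05). Transcript lengths were not compared between these lists, so the difference does not decide whether a loss of short transcripts was the cause. Fewer cycling cells stay open for both lists, which lay below the proliferation list by -0.56 (p = 1e-05) and -0.102 (p = 0.00138), but differed from the histones of S phase by -0.133 (permutation p = 0.0923) and, for the ribosomal proteins, by 0.325 (p = 1e-05). A change in the mix of cells and effects of glucose and of osmolarity were not tested and stay open.

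Single libraries departed from the other 2 of their group by a log2 value of at least 3, where those 2 lay within 1 of each other, in a few mRNA genes with at least 100 reads over the group, 9 of them in control 3, 8 in control 2, 7 in high glucose 1, 4 in control 1, 3 in high glucose 3 and 2 in high glucose 2.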
